A study of Mus musculus with 35 samples.

How the data were processed

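ATAC-seq was measured in 35 libraries of mouse HSCs and HPCs in 12 groups, on a B6 background per the series description, and each group had 1 pooled peak list. Groups were taken from the labels of cell type, age and genotype. Per the labels, nuclei were tagmented with Tn5 transposase, and the authors used Bowtie2 and MACS2 on the mouse build mm10 (GRCm38). Versions, settings, read depths and the way libraries were pooled are not given in the sources used here. The 8 lists of set 1 and the 4 lists of set 2 were of different kinds: the lowest -log10 p was about 1 in set 1 and about 2 in set 2. Knockout and wild type were therefore compared within set 2, and ages within set 1. The descriptions of 12 of the 24 libraries of set 1 name the peak list of another group than their title, whereas all 11 of set 2 name their own, and lists were assigned to groups by the group name that each list carries. The 12 include every library of P14 HSCs (3), P14 HPCs (2) and P21 HPCs (2), and 3 of the 5 of adult HSCs. Results for these groups therefore rest on the names of the lists.

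Each deposited list gives, per peak, a score from 413 to 1000, the fold (ratio) of the signal over the local background, a -log10 p and a -log10 q. These values are the authors' own, and they were used to describe, rank or filter regions within a list. The exception is the limit for strong adult regions, which was also applied to fetal lists in the test of long genes. Touching or overlapping peaks of a list on chromosomes 1 to 19, X and Y were merged into regions, and a region took the highest -log10 p of its peaks. A region was strong when its -log10 p lay in the upper 50% of its list. It was shared when at least 1 bp overlapped a region of the other list, and otherwise list-specific. Exact Clopper-Pearson intervals at 95% are given for shares of regions. They cover counting error only, since fragments without molecular identifiers are not independent molecules, and they do not cover differences between animals or libraries.

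The gene table used for GRCm38 gives chromosome, start and end of 21887 protein-coding genes without strand or exons. A region was therefore called at a gene end when it lay within 1 kb of either end of a gene, in place of the transcription start, and it was named by the gene with the nearest end within 50 kb. Introns, exons and untranslated regions were not analysed here. A search for transcription factor motifs had been planned and was not run, because no genome sequence was used here.

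The comparisons, alternatives, gene lists and the rule for naming genes were set before the data were examined. Named genes are, in each direction, those of the 10 list-specific regions with the highest -log10 p in the comparisons of age and genotype, and of the 5 highest between HSCs and HPCs and in the time courses, with 1 region per gene and predicted genes with numbered names left out. For each gene list, up to 3 members with a difference of at least 2 list-specific strong regions are added, and Lin28b, Hmga2, Igf2bp3, Mecom, Hlf, Ifnar1, Ifnar2, Isg15 and Irf7 are among those always included. The values of a few of these are given, the others follow the summaries, and some named genes are not reported here. The Isg15 region was picked out after its values were seen.

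The 17 gene lists held 286 members, all matched by symbol: the fetal programme, HSC regulators and markers, immediate early genes with AP-1, MHC and antigen presentation, type I interferon-stimulated genes, innate and cytokine receptors, lymphoid priming, the myeloid programme, the erythroid and megakaryocytic programme, the cell cycle, markers of hepatocytes, endothelium, stroma, T cells, B cells and macrophages, and non-haematopoietic regulators. For each list the net share was the number of strong regions in the first list alone minus that in the second alone, over all strong regions within the gene bodies and 10 kb on each side, counted as those in either list alone plus the mean number of shared regions in both lists. Its percentile was taken among 10000 random lists of equal size, drawn from protein-coding genes matched on their number of strong regions, and a list stood apart below percentile 0.5 or above 99.5. Genes and regions are not replicates, so a percentile describes these libraries only, and no p-value was computed.

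The adult position of a postnatal list used the strong fetal-specific and adult-specific regions of its cell type. The share of each kind present in the list was divided by the share of regions shared by fetus and adult that were matched on 10 classes of strength and on lying at a gene end, and the adult ratio was divided by the sum of both ratios. Its interval came from 200 bootstrap draws of regions. Regions lost in the knockout were compared in the same way with 1000 draws of matched regions that wild type and knockout shared.

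On simulated data, 500 strong regions removed from a copy of the fetal HSC list were all found against the original, with 0 false calls. This checks the code for overlaps and not how far 2 independent lists differ. A list of 25 genes that lost 0.1 of its regions stood apart in 15 of 20 runs and at larger losses in 20 of 20, and 1% of random lists stood apart. Adult positions set to 66.7%, 50% and 25% were returned as 66.9%, 48.8% and 25.5%. List-specific counts, adult positions of set 1 and regions lost in the knockout were recomputed with alternatives. These were -log10 q of at least 5, equal list lengths, 50% overlap of the shorter region, summits within 150 bp and autosomes only. The upper 25% or all regions were also taken as strong, except between both P7 wild-type HPC lists. Gene lists between ages and between genotypes were recomputed with gene ends, 50 kb windows, equal lengths and these other limits for strong regions. Gene lists between HSCs and HPCs, and age differences common to both cell types, were not recomputed. Of 62 alternatives set beforehand, those of the motif search and of leaving out replicates could not be run, and 5 were added after seeing the data. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with 1 as the seed of all random draws.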

Results

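Open chromatin was mapped by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in mouse haematopoietic stem cells (HSCs) and haematopoietic progenitor cells (HPCs). Set 1 held 24 libraries and 8 peak lists: fetal HSCs (3 libraries, E16.5, late gestation), HSCs at postnatal day 14 (P14; 3), adult HSCs (5, aged 8 weeks), fetal HPCs (3), and HPCs at P7 (3), P14 (2), P21 (2) and 8 weeks (3). Set 2 held 11 libraries and 4 peak lists at P7: wild-type HPCs (3) and HSCs (3), and HPCs (3) and HSCs (2) of mice labelled as knockouts of Ifnar, the receptor for type I interferon. The label spells it Infnar, and the title of 1 of the 3 knockout HPC libraries ends in the code of a wild-type library, so its place rests on its genotype label and description. The libraries of a group were pooled into 1 list, so no value below has a spread between replicates, and each holds for n = 1 list per group. Read depth per library is not given in the sources used here, and the length and strength of a list were the only measures of depth.

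After touching peaks were merged, a list held between 42463 regions (P7 knockout HSCs) and 91059 regions (P14 HPCs), which covered 24.9 to 56.9 Mb. The median -log10 p of a region, as the authors' peak caller gave it, ran from 29.2 in P7 HPCs of set 1 to 87.0 in P7 wild-type HPCs of set 2, with 44.8 in fetal and 83.0 in adult HSCs. Between 17.8% (adult HPCs) and 29.9% (P7 knockout HSCs) of regions lay within 1 kb of an end of a protein-coding gene. A region was called strong when its -log10 p was in the upper 50% of its own list, and list-specific when the other list had no region overlapping it. A region missing from a list was not called there, which is not the same as closed chromatin. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only.

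P7 wild-type HPCs were the only condition in both sets, and their lists were compared although the sets hold lists of different kinds and lengths, so the differences between them are not those of like lists. A region at the end of Zfp932, a zinc finger gene (mm10 chromosome 5, 109996076 to 109996824), was called with a -log10 p of 476 in set 1 and was missing from set 2. A region at Sf1, a splicing factor gene, and one near Tbc1d10c, both on chromosome 19, reached 1331 and 1152 in set 2 and were missing from set 1. Of the strong regions, 3920 (9.94%, 9.65 to 10.2) were in set 1 alone and 1428 (4.32%, 4.11 to 4.55) in set 2 alone, together 7.38% of strong regions. The Jaccard index of all regions (those shared over those in either list) was 0.599. Ebf1, a transcription factor gene of B cell development, had 3 strong regions in set 1 alone, and Dhx58, an RNA sensor gene, had 2 in set 2 alone. None of the 17 fixed gene lists stood apart from random lists in this comparison.

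The comparison of fetal with adult HSCs asked which regulatory regions of stem cells differ between the developing and the mature animal. Regions of adult HSCs that fetal HSCs lacked were led, after a 236 bp region nearest Col19a1 (-log10 p 4803), by regions near Pgr, the progesterone receptor gene (chromosome 9, 8895081 to 8895621, 834), Tcof1, a gene of ribosome biogenesis (chromosome 18, 60830419 to 60831535, 827), and Col27a1, a fibrillar collagen gene (chromosome 4, 63302431 to 63303087, 701). The Tcof1 and Col27a1 regions were in all 10 postnatal lists and in neither fetal list. Regions of fetal HSCs that adult HSCs lacked were led by one near Cdh8, a cadherin gene (chromosome 8, 98995669 to 98996559, 298), one in Cntnap5a (255) and one in Glra3, a glycine receptor gene (192). The Cdh8 region and one near Gabrg1, a GABA receptor gene (chromosome 5, 70842853 to 70843674, 163), were in both fetal lists and in none of the 10 postnatal lists. Others led by strength lay near Slc40a1, the iron exporter ferroportin (169), and Rnf19a (156), the latter called in 11 lists and missing from adult HSCs alone.

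Counted over the genome, 1556 strong regions (3.42%, 3.26 to 3.59) were in fetal HSCs alone and 2024 (4.53%, 4.33 to 4.72) in adult HSCs alone. With all regions the balance turned, to 20421 in fetal and 18815 in adult HSCs alone. Most strong list-specific regions lay more than 1 kb from a gene end. Within 1 kb lay 5.72% of the fetal-specific and 3.46% of the adult-specific ones, against 28.3% of shared strong regions. Together the list-specific ones were 3.97% of strong regions, and set 1 holds no pair of lists of 1 condition against which this share could be read.

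In the gene lists, the 25 HSC regulators and markers had 0 strong regions in fetal HSCs alone and 5 in adult HSCs alone (percentile 16.7 among random lists). Myeloid genes had 0 and 3 (percentile 1.12), innate and cytokine receptors 0 and 3 (4.59), type I interferon-stimulated genes 1 and 5 (4.62) and genes of MHC and antigen presentation 0 and 2 (6.88). Immediate early genes had 0 and 1 (37.2), lymphoid genes 3 and 2 (86.4), erythroid and megakaryocytic genes 1 and 0 (90.6), cell cycle genes 1 and 0 (80.7) and the fetal programme 1 and 1 (58.3). Markers of other cells moved little: hepatocytes 1 and 0 (93.4), endothelium 0 and 0 (58.2), stroma 1 and 1 (53.2), T cells 1 and 0 (83.9), B cells 0 and 0 (52.9), macrophages 1 and 1 (53.4) and non-haematopoietic regulators 0 and 1 (14.0). No list stood apart from the random lists. With all regions, an alternative chosen after seeing the data, the direction turned in myeloid genes (21 and 14, percentile 89.8), erythroid and megakaryocytic genes (5 and 14, 2.39) and non-haematopoietic regulators (13 and 12, 58.8). Dntt, the terminal transferase gene of early lymphoid cells, had 2 strong regions in adult HSCs alone. Within 10 kb of Hlf, a stem cell transcription factor gene, fetal HSCs had 8 regions and adult HSCs 14, and within 10 kb of Mecom they had 35 and 41.

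Fetal and adult HPCs were compared for the same question in progenitors. Genes that regulate or mark HSCs had more open regions in adult HPCs: 17 strong regions in their windows were in adult HPCs alone and 4 in fetal HPCs alone, of 122.5 strong regions (those in 1 list alone plus the mean number of shared ones). Mecom, a transcription factor gene of stem cells, had 3 adult-specific regions and no fetal-specific one, Prdm16 had 3 and 1, and Lmo2 and Vwf had 2 and 0. The net share was -10.6%, at percentile 0.325 of random gene lists, and this was the only one of 68 tests of a list (17 lists in 4 comparisons) to stand apart. On simulated data 1% of random lists stood apart, so 1 such call in 68 tests may arise from random lists alone. The call was also lost under some alternatives, given below. Lin28b, which encodes a fetal RNA-binding protein, went the other way, with 2 strong regions in fetal HPCs alone and 11 regions of any strength in fetal against 4 in adult HPCs. By strength, adult-specific regions were led by those near Hjurp, a centromere chaperone gene (654), Tcof1 (610), Pdlim5 (564) and Ell2, an elongation factor gene (522). Fetal-specific regions were led by those near Peg3, an imprinted gene (chromosome 7, 6728163 to 6729039, 357), and in Cd226, a receptor gene of T and natural killer cells (316).

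In all, 2465 strong regions (5.45%, 5.24 to 5.66) were in fetal HPCs alone and 2889 (6.37%, 6.15 to 6.60) in adult HPCs alone, together 5.91%. With all regions the balance turned here too, to 22852 in fetal and 22480 in adult HPCs alone. Within 1 kb of gene ends lay 7.22% of the fetal-specific, 4.40% of the adult-specific and 28.0% of the shared strong regions. Ikzf1, a lymphoid transcription factor gene, had 2 strong regions in fetal HPCs alone, whereas Ebf1, Bcl11a, Mef2c, Ifi44, Lepr and Cd5l each had 2, and Ciita, the switch of MHC class II genes, had 3, in adult HPCs alone. Erythroid and megakaryocytic genes had 3 fetal-specific and 0 adult-specific regions (percentile 97.6), stromal markers 0 and 3 (1.22), B cell markers 0 and 2 (3.54) and interferon-stimulated genes 5 and 4 (73.7), and the 12 lists not named here lay between percentiles 6.37 and 86.4. Again with all regions, the direction turned in interferon-stimulated genes (18 and 34, percentile 1.32), B cell markers (8 and 7, 57.7) and myeloid genes (17 and 23, 14.9, from 3 and 2). The result for HSC regulators ended when only regions within 1 kb of a gene end were used (percentile 46.4), with the upper 25% of each list as strong regions (28.7), and with all regions, an alternative chosen after seeing the data (7.10). It stood apart at equal list lengths (0.185) and with windows of 50 kb (0.480).

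**Figure D1:**
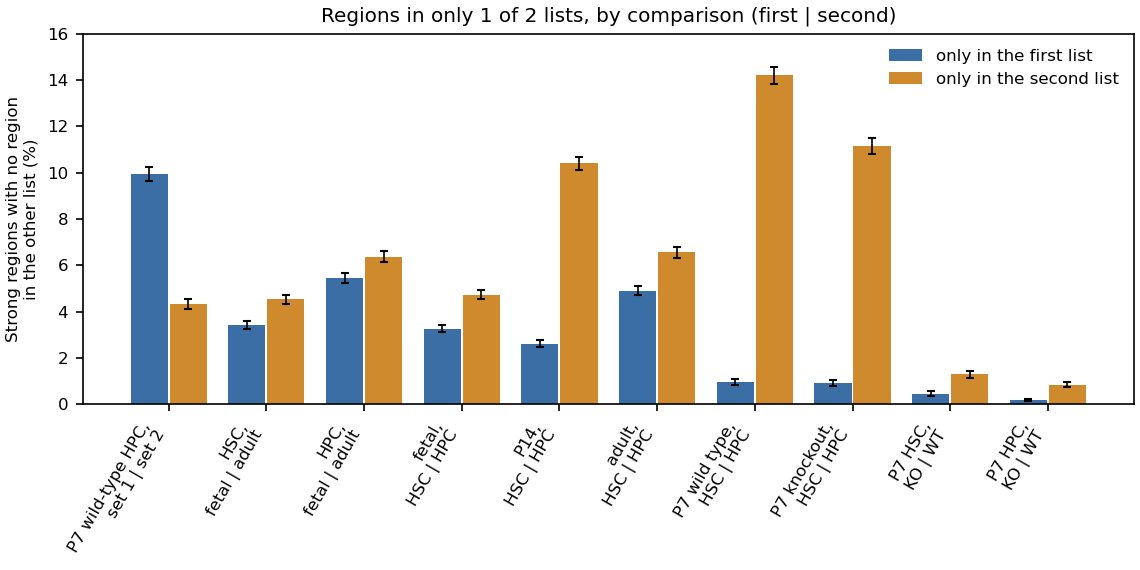
Percent of strong regions (upper 50% of a list by -log10 p) that were in the first list alone or in the second list alone, for each of 10 comparisons, with exact 95% intervals of counting error as lines. With both directions summed, knockout and wild type differed least (0.892% of strong regions in HSCs, 0.528% in HPCs), and P7 wild-type HPCs had 14.2% of strong regions that HSCs lacked.

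How postnatal cells lie between the fetal and the adult state was asked with the strong fetal-specific and adult-specific regions of each cell type. Of the adult-specific HSC regions, the strongest that were called at P14 lay near Tcof1, Col27a1, Lrrc58, Wdr38 and Col16a1, while those nearest Col19a1 and Pgr were not called there. Of the fetal-specific ones, the strongest missing at P14 lay near Cdh8, Cntnap5a, Glra3, Gucy1a2 and Gabrg1, while those near Prss23, Slc40a1, Snph and Rnf19a were called. Picked in the same way, the HPC lists of set 1 had the adult-specific regions near Hjurp, Tcof1, Pdlim5, Ell2 and Mgat4b from P7 on, and they lacked the fetal-specific regions near Lmo1, a LIM-domain gene, and Esf1 at P7, P14 and P21. Both P7 HPC lists of set 2 had 4 of these 5 adult-specific regions, while the Ell2 region was in that of the wild type alone and the Lmo1 (39.2) and Esf1 (56.3) regions in that of the knockout alone. Adult HSCs had the Lmo1 and Esf1 regions too (405 and 141), so they were fetal-specific among HPCs only. In P14 HSCs, 34.1% of fetal-specific and 49.5% of adult-specific regions were present, against 83.3% and 84.4% of shared regions matched in strength. The HPC lists of set 1 held 47.8% of fetal-specific and 68.2% of adult-specific regions at P7, 53.5% and 85.1% at P14, and 32.8% and 73.0% at P21.

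Dividing each share by that of matched shared regions gave an adult position, the adult part of the sum of both ratios, where 0% is fetal and 100% adult. It was 58.9% (bootstrap 95% interval 56.6 to 60.9) in P14 HSCs. In HPCs it was 58.1% (56.9 to 59.3) at P7, 61.1% (60.3 to 62.0) at P14 and 68.4% (67.1 to 69.8) at P21. Among the P7 lists of set 2, wild-type HPCs lay at 65.5% (64.1 to 67.3) and wild-type HSCs at 42.7% (39.1 to 46.0). The gap between the set 1 and set 2 lists of P7 wild-type HPCs is about as large as the step from P14 to P21, and the intervals do not cover differences of this kind. The P14 and P21 lists were assigned by their names, against the descriptions of all libraries of these groups, so the order of ages rests on those names.

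**Figure D2:**
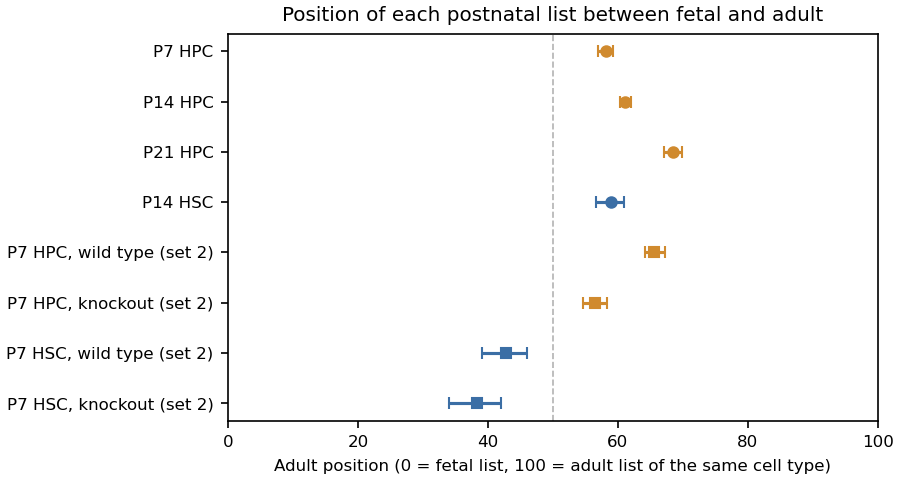
Adult position in percent (0 fetal, 100 adult) of 8 postnatal lists, with 95% bootstrap intervals over regions as lines; the dashed line marks 50. HPCs of set 1 lay at 58.1% at P7, 61.1% at P14 and 68.4% at P21, and P7 HSCs of set 2 lay below 50.

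HSCs and HPCs of 1 age were compared to find regions that part stem cells from progenitors. Regions near Ptger2, a prostaglandin E2 receptor gene (chromosome 14, 45011218 to 45011779), and Panx1, a membrane channel gene (chromosome 9, 15017913 to 15018655), were called in all 7 HPC lists. At P7 they reached -log10 p values of 1324 and 1248 in wild-type and 719.9 and 715 in knockout HPCs and were missing from both HSC lists of that age. The Ptger2 region was also missing from P14 HSCs and the Panx1 region from fetal HSCs, while adult HSCs had both, at 231 and 212. A region near Ccdc93 (chromosome 1, 121477978 to 121478969) was in all 7 HPC lists and in none of the 5 HSC lists, at 1099.9 in adult HPCs. HSC-specific regions in adults were led by those near Gnaz, a G protein gene (1041), Cdh11, a cadherin gene (1016), and Cavin2, a gene of caveolae (995).

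Cdk6, a cell cycle kinase gene, had 2 strong regions in HPCs alone in the fetus, 3 at P14, 2 in adults, 3 in P7 wild-type and 2 in P7 knockout mice, and none in HSCs alone at any of these ages. Ebf1 had 5 HPC-specific regions at P14, 3 in adults and 3 in P7 wild-type mice. In P7 wild-type mice, macrophage markers had 6 strong regions in HPCs alone and 0 in HSCs alone (percentile 0.0900), among them 3 at Cd5l and 2 at Marco. B cell markers had 4 and 0 (percentile 0.185), and the erythroid and megakaryocytic genes had 0 and 1 (99.55). None of the 17 lists stood apart in fetal, P14, adult or P7 knockout mice. Macrophage markers held 16 strong regions in wild-type HPCs of set 2, but 9 in the set 1 list of the same condition and 9 in knockout HPCs. All 17 lists were tested in each of these comparisons, and 1% of random lists stood apart on simulated data. Some of the calls in P7 wild-type mice may therefore arise from random lists alone. These tests between HSCs and HPCs were not repeated at equal list length.

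The strong regions in HSCs alone and in HPCs alone numbered 1486 (3.27%) and 2136 (4.72%) in the fetus, 961 (2.62%) and 4739 (10.4%) at P14, and 2191 (4.90%) and 2974 (6.56%) in adults. With all regions the balance turned in the fetus (21794 and 20470) and in adults (21039 and 20894). At P7 the strong ones numbered 221 (0.969%) and 4690 (14.2%) in wild-type mice and 191 (0.90%) and 3265 (11.1%) in knockouts. The HSC lists of P7 and P14 were shorter than the HPC lists, and taking equally many regions from both lists gave 582 and 1999 regions in P7 wild-type, 421 and 1319 in P7 knockout and 1507 and 2662 in P14 mice.

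Whether chromatin at P7 depends on interferon signalling was asked by comparing knockout with wild-type HSCs. A region near Hunk, a kinase gene (chromosome 16, 90349621 to 90350190, -log10 p 248), was called in 10 lists and was missing from both knockout lists. A region nearest Mid1 (chromosome X, 169996861 to 169997384, 264) was called in both knockout lists and in no other list. Wild-type HSCs also had regions near Ltc4s, the leukotriene C4 synthase gene (274), Brd3os (233) and Pik3r3, a kinase subunit gene (183), each of which was missing from knockout HSCs and from no other list. Knockout HSCs had the Zfp932 region (244) and one in Pex3, a peroxisome gene (130), that wild-type HSCs lacked. The Zfp932 region was also missing from wild-type HPCs of set 2 but was called in those of set 1 (476), so its calls did not follow genotype alone. A region at an end of Isg15, a gene induced by interferon (chromosome 4, 156200723 to 156200990), was called in wild-type HSCs (34.0) and HPCs (28.7) and in neither knockout list. It was below the limit for strong regions in both wild-type lists (66.8 and 87.0), and of all regions, 8924 of wild-type HSCs and 13061 of wild-type HPCs were missing from the knockout. It was also missing from both fetal lists and present in the other 6 postnatal lists, with 75.7 in adult HSCs.

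Few strong regions differed: 98 (0.462%, 0.375 to 0.562) were in knockout HSCs alone and 295 (1.29%, 1.15 to 1.45) in wild-type HSCs alone, a Jaccard index of 0.719. Interferon-stimulated genes had 0 strong regions in knockout HSCs alone and 1 in wild-type HSCs alone (percentile 18.7). HSC regulators had 1 and 0 (95.1), cell cycle genes 0 and 1 (23.6) and endothelial markers 0 and 1 (7.84), and the other 13 lists had none. HSC regulators turned to the wild type with all regions (19 and 37, percentile 26.1). Regions at the gene ends of Ifnar1 and Ifnar2 were called in all 12 lists, which says nothing about the deleted sequence itself. The knockout list was shorter, and at equal list length 100 regions were in knockout and 181 in wild-type HSCs alone.

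In HPCs the same question gave the regions near Hunk (322) and one nearest Vps26c (chromosome 16, 94484850 to 94485585, 237) as lost in the knockout, both missing from both knockout lists and present in the other 10. A region near Igf1r, the receptor gene for insulin-like growth factor (169.9), was missing from knockout HPCs alone, and one near Nfkb1, an inflammatory transcription factor gene (168), from both knockout lists. Knockout HPCs had the Mid1 region (422), the Zfp932 region (369) and another region nearest Vps26c (chromosome 16, 94509994 to 94510577, 221) that wild-type HPCs lacked. Hunk and Vps26c lie on chromosome 16, which also carries Ifnar1. The region nearest Col19a1 (chromosome 1, 24612996 to 24613236, 241 bp wide) had the highest -log10 p of all wild-type regions missing from a knockout list, 2492 in HSCs and 2818 in HPCs. It was also missing from fetal HSCs, P14 HSCs and P21 HPCs, so its calls did not follow genotype, age or cell type.

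In HPCs, 50 strong regions (0.171%, 0.127 to 0.225) were in the knockout alone and 279 (0.845%, 0.749 to 0.949) in the wild type alone, a Jaccard index of 0.739. Interferon-stimulated genes had 0 and 1 (percentile 2.55), lymphoid genes 0 and 1 (15.5) and myeloid genes 0 and 1 (1.18), and the other 14 lists had none. At equal list length the counts were 52 and 126. Among 22589 strong regions of wild-type HSCs that wild-type HPCs shared, 12 (6.20 to 20.96) were lost in both cell types, where independent losses would give 1.71 and losses independent within classes of strength and position 4.75. At equal list length 6 were lost in both. The region near Hunk on chromosome 16, which carries Ifnar1, was among the 12, and the count was not repeated without that chromosome.

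**Figure D3:**
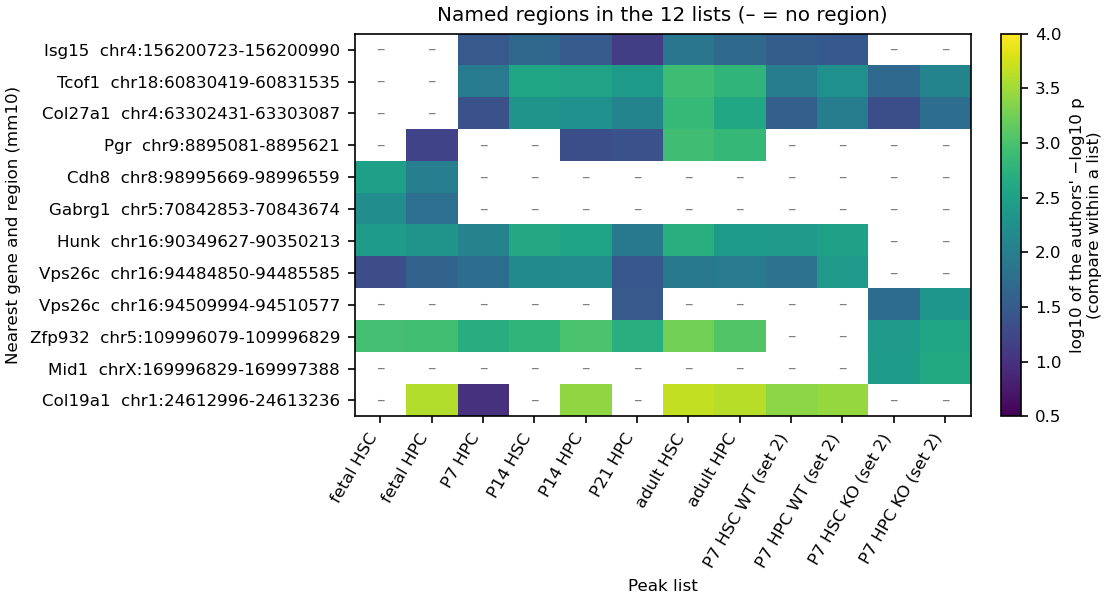
Authors' -log10 p (colour, log10 scale) of 12 regions, labelled by nearest gene, in the 12 peak lists, with a dash where a list had no region. The Tcof1 and Col27a1 regions were in all 10 postnatal lists, the Cdh8 and Gabrg1 regions in both fetal lists alone, and the Mid1 region in both knockout lists alone.

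The last comparison asked whether regions lost with the interferon receptor were those of the adult or the fetal state. Of the 279 strong regions lost in knockout HPCs, 196 (70.3%) were in the fetal HPC list, against 87.2% of matched regions that wild type and knockout shared, a difference of -17.0 points and below each of 1000 draws. In the adult HPC list the lost regions were about as frequent as matched ones, 90.3% against 92.5% (percentile 10). Counting the 74 lost regions that were in exactly 1 of the fetal and adult lists, 65 (87.8%) were in the adult list, against 69.4% of matched regions (percentile 100), a test chosen after seeing the data. In HSCs, 94.9% of the 295 lost regions were in the adult and 95.9% in the fetal list, against 97.7% (percentile 0.2) and 98.4% (0.4) of matched regions. Of the 25 lost HSC regions in exactly 1 age list, 11 (44%) were in the adult list, against 37.8% of matched regions (percentile 73.3). The adult position of knockout HPCs was 56.4% (54.7 to 58.3), below the 65.5% of wild-type HPCs, and that of knockout HSCs 38.3% (34.0 to 42.0), below 42.7% (39.1 to 46.0) with overlapping intervals. The set 1 list of P7 wild-type HPCs lay at 58.1% (56.9 to 59.3), and its interval overlapped that of knockout HPCs. At equal list length, a setting chosen for the positions after seeing the data, the HPC difference was 8.87 points and the HSC difference 2.37 points. There the fetal shortfall of lost HPC regions was -25.8 points, that of lost HSC regions -9.99 points, and the adult shortfall in HSCs no longer stood apart (-6.57 points). With the upper 25% of each list as strong regions, 4 lost HPC and 10 lost HSC regions remained, and the HPC difference in the fetal list was 2.03 points.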

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

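All of these settings were chosen before the data were examined except leaving out chromosome 16, equal lengths for the P7 adult positions of set 2 and all regions for gene lists, which were chosen after seeing the data. No paired analysis was possible because each group had 1 pooled list, and for that reason no replicate was left out. Motif alternatives were not run, because no genome sequence was used here. A count was kept when it stayed near its first value, and an adult position when it stayed within its first interval. A share of lost regions was kept when its call, and the direction of a call, stayed. Other values, such as the share of each side and single gene lists, are not among these results. Over all settings those were the same in 400 cases, moved in 25, reversed in 4, stronger in 9 and weaker in 3. All 19 results recomputed with -log10 q of at least 5 were kept, as were 19 with 50% overlap of the shorter region and 19 with summits within 150 bp. So were 19 on autosomes only and 6 on knockout and wild type without chromosome 16. The call lost without it was that of interferon-stimulated genes in HSCs with all regions (percentile 0.450, then 1.19, with net shares of -17.9% and -17.0%).

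With lists of equal length, 14 of 20 results were kept. List-specific strong regions numbered 2581 (HSCs against HPCs, P7 wild type), 1740 (P7 knockout) and 178 (knockout against wild type, HPCs), regions lost in both cell types 6, the adult position of P14 HSCs 61.5%, and the adult shortfall of regions lost in knockout HSCs -6.57 points, which no longer stood apart; the cause was not tested.

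Counts scale with the number of regions called strong. With the upper 25% they were 472 and 640 between fetus and adult (HSCs, HPCs), 350, 768, 809, 958 and 488 between HSCs and HPCs (fetal, P14, adult, P7 wild type, P7 knockout), 13 and 7 between knockout and wild type (HSCs, HPCs) and 2 lost in both cell types. With all regions the same counts were 39236, 45332, 42264, 40064, 41933, 29426, 25310, 14404, 18726 and 1249. The adult positions of P14 HSCs and of P7, P14 and P21 HPCs were 69.5%, 59.5%, 64.5% and 76.5% with the upper 25% and 53.4%, 61.7%, 62.6% and 66.8% with all regions. The fetal-specific part of the regions that differed between fetus and adult rose above 50% with all regions, to 52.0% in HSCs and 50.4% in HPCs, as did the HSC-specific part in the fetus (51.6%) and in adults (50.2%); the cause was not tested.

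Of the regions lost in the knockout, the upper 25% left 10 in HSCs and 4 in HPCs. Their difference from matched regions was then 0.540 points in the adult and -9.62 points in the fetal list for HSCs and 2.03 points in the fetal list for HPCs, and too few regions remained to read a direction. The share in the adult list among regions in 1 of the 2 age lists gave no value there. With all regions the adult shortfall in HPCs came to stand apart, at -4.08 points, where 13061 regions narrow the matched range.

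Of 68 gene list tests, 1 stood apart at first, 4 with regions at gene ends only, 3 with all regions and 1 with the upper 25%, which was the fetal programme in HSCs (99.8, from 1 region) in place of HSC regulators in HPCs. At gene ends these were the fetal programme (99.6), interferon-stimulated genes (0.0750) and myeloid genes (0.0200) in HSCs and endothelial markers (99.6) in HPCs, each between fetus and adult and each resting on 1 or 2 regions. Read depth is not given in the sources used here, so how far it limits the lists was not tested.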

Other observations

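The tests chosen only after their result was seen are the gene lists with all regions, the regions of postnatal lists with the receptor, the age list shares among regions in 1 of the 2 age lists, and the tests around Ifnar1. With regions of any strength, HSC regulators and markers had 34 regions in fetal HSCs alone and 79 in adult HSCs alone, a net share of -13.5% (percentile 0.430 among random lists). Meis1, a homeobox gene of stem cells, had 1 and 7, Hlf 0 and 6, Fli1 1 and 6, Mecom 5 and 12, and Mllt3 5 and 11. The fetal programme went the other way in HPCs, with 27 regions in fetal and 9 in adult HPCs alone (percentile 99.8), among them 7 and 0 at Lin28b, 5 and 1 at Hmga2, 4 and 1 at Arid3a and 3 and 0 at Igf2bp2. In HSCs the fetal programme had 18 and 13 (81.1). Type I interferon-stimulated genes had 5 regions in P7 knockout HSCs alone and 24 in wild-type HSCs alone, with 18 of 38 genes having more in the wild type and 3 more in the knockout (percentile 0.450). Ifit2, Mx2, Ifi27 and Ifih1 had 0 and 2 each. Without the members on chromosome 16, which carries Ifnar1, the remaining 34 genes had 5 and 21 and no longer stood apart (percentile 1.19), although the net share hardly moved, from -17.9% to -17.0%. In HPCs the same genes had 10 and 13 (84.5), and whether the cell types differ was not tested. Between both lists of P7 wild-type HPCs, none of the 17 lists stood apart with all regions.

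Regions missing at the other age in 1 cell type were often missing there in the other cell type too. Of strong fetal HSC regions that fetal HPCs shared, 674 were missing from both adult lists, where independent losses within classes of strength and position would give 147, and 847 adult regions were missing from both fetal lists, against 145. Of 33858 regions called in all 8 postnatal lists with the receptor, 19 were missing from both fetal and both knockout lists, among them those at Isg15, Itsn1, Rb1, Foxn3 and Elovl5. Of the 19, 1 (5.26%) lay within 10 kb of an interferon-stimulated gene, against 0.226% of matched regions. This share did not stand apart (percentile 97.85). The Itsn1 region lies on chromosome 16, which also carries Ifnar1. How many such regions would arise without a role of the receptor was not tested.

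HPC regions lost in the knockout were in the fetal list less often than matched regions and leaned to the adult list. The length of the knockout list alone was argued against, since the shortfall was -25.8 points with lists of equal length (50.8% of 126 lost regions against 76.6% of matched ones). That setting shortened the fetal list as well. It did not make the strength of the lists equal (median -log10 p 78.4 in knockout and 87.0 in wild-type HPCs), so a weaker knockout list was not tested. Differences between lists of 1 condition stay open. The only such pair crosses both sets, and wild-type regions of set 2 that set 1 lacked fell short in its fetal list (-34.9 points) and its adult list (-29.9 points) alike and by -9.09 points in adult share among regions in 1 of the 2 age lists, while set 1 regions that set 2 lacked gave -0.727 points in the fetal list. A need for the interferon receptor in adult-type regions stays open: the 50 regions gained in the knockout were in the adult list less often than matched ones (-25.2 points), yet in the fetal list they were not more frequent (-5.85 points).

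Knockout and wild-type lists differed near Ifnar1, the gene of 1 receptor subunit; which subunit is deleted is not given in the sources used here. The 10 Mb on each side held 15 list-specific strong regions of HSCs and HPCs against 5.37 in matched draws, or 12 against 5.32 with regions of both cell types counted once, and either way 0 of 249 windows over the genome (0%) had an excess as large. HPC regions alone gave 0 of 217 windows and HSC regions alone 17 of 232. DNA of another strain around the knocked-out locus may account for this if Ifnar1 or a neighbour is the deleted gene, and no sequence was used here to test it. Interferon-stimulated genes in the window stay open: 1 of the 15 regions lay within 50 kb of such a gene of the fixed list. Few members of that list lie on chromosome 16, so the count could hardly be high and does not decide the question.

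Fetal-specific regions lay in genes of at least 500 kb in 9.90% (HSCs) and 8.44% (HPCs), above the 5.98% and 5.16% of adult-specific regions with separate intervals. Gene length alone would place regions of both ages in such genes about as often. The pattern was seen in these same regions, so the shares describe it and are no independent test of gene length. The lower strength of the fetal lists stays open. Among fetal-specific regions above the limit for strong adult regions, the shares were still 11.8% and 8.57%. That limit puts -log10 p values of different lists on a common scale, which their differing strength does not allow. Differences between lists of 1 condition stay open, since the only such pair crosses both sets: 11.3% of the regions in set 1 alone of P7 wild-type HPCs lay in such genes, and 0.210% of those in set 2 alone. The age of the cells stays open too.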
